A study of Mus musculus with 16 samples.

How the data were processed

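Genomic DNA from the tails of C57BL/6 mice was compared on 2-colour arrays for comparative genomic hybridisation, in which DNA of a test mouse and of a reference mouse carry different dyes and compete for the same probes. The series holds 16 arrays. They cover 8 mice of a single family, namely a male parent, a female parent and 6 progeny, each hybridised on 2 arrays with the dyes exchanged. The reference DNA on every array came from mouse 9, a male of the same colony. Per the labels, the red dye was Cy5 and the green dye was Cy3 on all arrays, and the mouse and the reference changed places between the 2 arrays of a pair. The 2 arrays of a mouse hold the same DNA, so a mouse counted as 1 replicate.

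Per the file headers, the scanner images were quantified with Feature Extraction 10.7.1.1 on a design with mm9 (NCBI37) coordinates. The deposited processed signals are intensity values from which background had been subtracted and whose dyes had been scaled by a linear factor, with no lowess step, per the file headers. The deposited log ratio column is the log10 of red over green. The red over green ratio taken here from the processed signals differed from it by at most 0.311 on the log2 scale at any spot. A table of the whole series holds 1 column per array, and the deposited values in it read as log2 ratios with column medians between -0.00495 and 0.0146. How the authors scaled and centred that table is not given in the sources used here. Its X chromosome medians in the columns of the female parent were -0.97 and -0.92, so all of its columns were read as reference over mouse.

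The table and the scanner files do not hold the same measurements. After the mean of each probe over arrays of the same dye orientation had been removed, a column and the scanner file of the same label correlated with a median absolute r of 0.0318 across autosomal probes, against 0.0219 for files of other labels. Probes are not independent replicates, and these coefficients describe the arrays only. The scanner files were used for every value in the results, and the table as an alternative. Which source holds the labelled family is unknown.

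Of 973116 spots per array, 6745 control spots were left out, and between 124 and 239 spots flagged as outliers were left out on each array. Spots of the same probe were averaged, which left 950622 probes on the autosomes, 68 on X and 23 on Y. The autosomal probes lie a median of 2053 bp apart. For 98.9% of them, both channels were well above background on all 16 arrays. The log2 ratios were turned to mouse over reference, centred on the autosomal median of each array, and averaged over the 2 arrays of a mouse. No loess or quantile step was applied. Arrays of the same orientation correlated positively, with r between 0.20 and 0.47 across autosomal probes, and the 2 arrays of a mouse, of opposite orientation, with r between -0.39 and -0.06, so a dye effect shared by arrays exceeds the signal of most probes and cancels only in the mean of both.

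Each mouse was scanned for intervals of at least 3 probes whose sum deviated from 0 by a z of 6 or more, up to 1000 probes long, with the noise taken from differences between neighbouring probes. Neighbouring calls of the same direction at most 5 probes apart were joined. A call needed an absolute mean log2 ratio of at least 0.25 and the same sign in both orientations, each at 0.5 times that size or more. Calls of different mice formed a region where they shared at least 0.5 of the probes of each. A mouse carried a region where its mean exceeded 0.5 of the mean over the called mice, lacked it below 0.25, and was unclear between. False calls were counted on a noise track made for each mouse from 0.5 times the difference between its 2 orientations, less the mean dye difference of each probe. As a mean of both orientations, that track has the noise of the arrays and no copy number signal. Any other difference that follows the DNA of the mouse in both orientations cancels as well. False calls from such differences are not counted on it. In a single orientation the copy number signal does not cancel, so the track's counts there are not noise alone. The score of a call is its mean in units of its expected noise.

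With 2 arrays of the same DNA per mouse there is no p-value for a mouse. Errors of region means are standard errors over probes, and the values of both arrays are in the results. The 6 progeny were compared with the 2 parents by limma 3.58.1 (R 4.3.3) on 1 value per mouse and autosomal probe, with a Benjamini-Hochberg threshold of 0.05, two-sided. The scan was tested on simulated segments placed in the noise tracks of the 8 mice, 40 for each combination of size and shift across 950622 probes. It found 100% of 3-probe segments at a log2 shift of -1, 100% at 0.58 and 27.5% at 0.3. At 10 probes it found 90% of the segments at 0.3. These shares hold for calls at a z of 6 and not for the limit at the highest score of the noise track. In the limma comparison on 100000 simulated probes, 70.1% of the probes shifted by 0.5, 97.0% of those shifted by 1 and 98.5% of those shifted by 2 passed. The shifts were given to all 6 progeny alike, in 67, 67 and 66 probes, and 9 unshifted probes passed too. These shares need not hold for the 950620 probes of the data or for changes in fewer progeny. Python 3.11.15, numpy 2.4.6 and numba 0.67.0 were used for the scan.

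Before the data were examined, the regions to be named were fixed as the 12 highest-scoring regions in progeny and in neither parent, the 10 with the largest mean log2 ratio, the 5 carried by a parent that have the most probes, and the 5 X regions with the largest mean, along with the 5 strongest single probes. The limit at the highest score of the noise track was chosen after seeing the data, and so were regions named only because they exceed it, the bounds for reading the tests of explanations, and the rule that picks out signals of the series table. Alternatives were normexp background correction with an offset of 50 on median spot and background signals, in place of mean signals, the series table, leaving out dim probes, another centring, removal of slow waves along chromosomes, stricter and looser scan settings, a single dye orientation, and leaving out mice. Scan days and months were taken from the file headers and numbered. Both parents were scanned on day 1 and the progeny on days 2 to 4, so day and generation cannot be told apart, while month 1 held both parents and progeny 1 and 2.

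Probes are given by position on mm9. The gene table at hand belongs to GRCm38, and the files pair probes with positions only, so no gene is named. The test of gene lists fixed in advance was therefore not run. For ratios given as bounds, a reading not well above background was replaced by the lowest signal of a probe well above background. That signal came from the same channel of the same array and was used only if it was higher. Other region means keep the processed signals as measured.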

Results

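DNA copy number was measured in the tails of a male parent, a female parent and their 6 progeny, each against the same reference male. The series' title concerns offspring of males under continuous gamma irradiation at 1 mGy per day over 400 days, whereas its design text describes the male parent of this family as not irradiated. The labels do not settle which holds. No family with another exposure was analysed here, so the values describe this family and make no comparison between exposures. Probe noise after averaging both arrays lay between 0.0976 in progeny 2 and 0.139 in progeny 3 on the log2 scale, and the signal-to-noise ratio of the arrays between 41.4 and 77.4. All values come from the scanner files. The series table, under the same labels, held other values at several of the regions below, and the closing section gives the main ones.

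The X chromosome gave the response of the arrays to a known difference. In the female parent the median log2 ratio over 68 X probes was 0.94 ± 0.021 (SE over probes), from 0.97 and 0.91 on its 2 arrays, where 2 copies against 1 would give 1. The male parent stood at -0.02. Progeny 1 to 4 lay between -0.00194 and 0.0157, while progeny 5 was at 0.98 and progeny 6 at 1.01. The labels do not give the sex of the progeny. Over 23 Y probes the median log2 ratio was at most -1.72 in the female parent, -2.23 in progeny 5 and -1.97 in progeny 6, as bounds, since 31, 13 and 14 of their 46 readings were well above background, and it was between -0.06 and 0.08 in the other mice. No median of an autosome departed from 0 by more than 0.0214 in any mouse. No region was called on X after each mouse had been centred on its own X median. The X probes lie a median of 820281 bp apart, so a call there needs a far longer change than on the autosomes.

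The question of the design was which copy number changes appear in progeny without being present in either parent. A loss on chromosome 14 in progeny 5 was the clearest of them. It spanned 38289134 to 38430438 (mm9), which is 141 kb and 54 probes, and all 54 probes were below -0.5 in that mouse. The mean log2 ratio was -0.97 ± 0.021 (SE over probes), with -0.95 and -0.99 on the 2 arrays, where 1 copy against 2 would give -1. The male parent had 0.03 ± 0.018 and the female parent 0.04 ± 0.017 over the same probes, and no other progeny mouse exceeded 0.0508 in absolute size. The last probe before the loss ended at 38286788 and the first after it began at 38441107, which bounds both breakpoints. The flanks of the same mouse lay at 0.0013 and -0.017.

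In all, 410 regions were called in progeny and in neither parent, whereas the noise track gave 571. The count as such did not exceed that of the noise track in this setting, but the tracks were not treated alike. Each probe's mean over the 8 mice was removed from the noise track only. Offsets shared by parents and progeny thus stay in the ratios and can take regions out of this class. The highest score on the noise track was 13.8, and the chromosome 14 loss, at -57.2, was the only one of these regions beyond it. That limit was set by a 3-probe noise call, while the 1 noise call of 10 or more probes scored 9.02. A score grows with the number of probes, so a short change of 1 copy can stay below the limit. Next by score was a 3-probe loss on chromosome 13 from 60076590 to 60080810 in progeny 1, with a mean of -0.72 and a score of -12.5, followed by a 3-probe gain on chromosome 2 from 134348842 to 134352073 in the same mouse, with 0.69. The remaining regions among the 12 highest had scores of at most 11.8 in absolute size, and of these only a loss on chromosome 1 from 178991541 to 179003341 in progeny 6 held more than 3 probes, with 6 probes at -0.51. None of the 11 below the chromosome 14 loss can be told from noise by that limit. The 6-probe loss, with a score of -10.4, did exceed the 9.2 reached by noise calls of 5 to 9 probes, but was at -0.046 with normexp. In all 11, part of the readings on the dimmer side were not well above background, and with normexp their values lay between -0.113 and 0.0807. The offset of normexp compresses ratios over dim readings whether they are real or not. The normexp values, that of the 6-probe loss among them, therefore cannot decide whether these regions are real. In 5 other settings the count stood above the noise track. It was 31 against 13 with normexp, 88 against 78 without dim probes and 242 against 224 at a log2 of 0.4. In the series table it was 863 against 767. After subtracting the median over the 8 mice, which was done for both tracks, it was 762 against 564.

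A gain on chromosome 12 was shared by 3 of the 6 progeny. It ran from 82569904 to 83525774, 956 kb and 412 probes, and had the highest score of all regions, 113. It was singled out after its values were seen. Progeny 2 had a mean log2 ratio of 0.54 ± 0.0056, progeny 4 of 0.56 ± 0.0055 and progeny 5 of 0.54 ± 0.0066 (SE over probes), where 3 copies against 2 would give 0.58. Progeny 1, 3 and 6 lay between -0.0337 and -0.00509 and the male parent at -0.01 ± 0.0056. The female parent was between these levels, at 0.17 ± 0.0058, with 0.16 and 0.19 on its 2 arrays, so that its state is unclear under the rule for carriers and the region was not counted among those in neither parent.

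**Figure D1:**
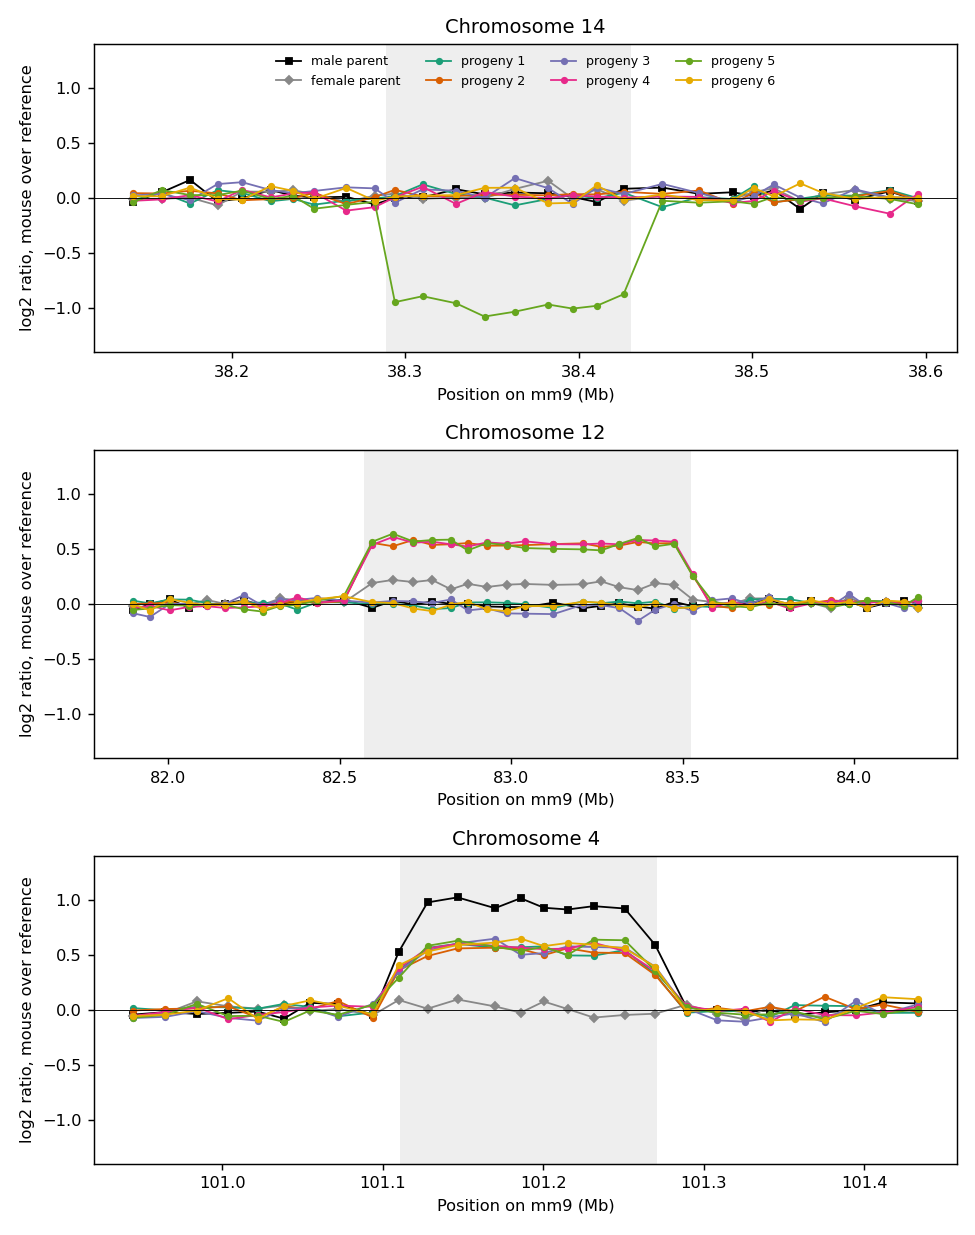
Mean log2 ratio of mouse over reference (vertical axis) against position on mm9 in Mb (horizontal axis) for the chromosome 14 loss, the chromosome 12 gain and the chromosome 4 gain, with a line and points per mouse, each point a mean over neighbouring probes, and the region shaded. Progeny 5 alone falls to -0.97 on chromosome 14, the female parent lies at 0.17 on chromosome 12 between the carriers and the other mice, and on chromosome 4 the male parent at 0.95 lies above all 6 progeny.

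Under the labels of the scanner files, 2 regions were higher than the reference in the male parent and, at lower levels, in all progeny. On chromosome 4, from 101110482 to 101270535 (160 kb, 74 probes), the male parent had a mean log2 ratio of 0.95 ± 0.013 (SE over probes), near the value of 1 for 4 copies against 2. The progeny had 0.56 ± 0.02 (SD, n = 6), near the 0.58 of 3 copies against 2, and ranged from 0.53 to 0.59. The female parent had 0.01 ± 0.014. The distance between the male parent and the nearest progeny mouse was many times the SD among progeny, although a single male parent allows no test.

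A 6.1 kb segment on chromosome 2, from 70079530 to 70085630, was measured in the male parent and all progeny but neither in the female parent nor in the reference. None of the 8 readings of its 4 probes in the female parent was well above background, nor were any but 1 of the 64 readings of the reference, the exception lying on an array of progeny 2. The processed signal was 1579 in the male parent and 785 ± 13.8 (SD, n = 6) in the progeny, a ratio of 2.01, or 2.02 after dividing by the median signal of each array channel. Against the floor set by the background, the male parent was at least 16.2-fold above the reference, and the bounds of single progeny mice ran from 6.54-fold to 9.38-fold. With normexp, whose offset compresses ratios over dim readings, the mean log2 ratio of the 7 carriers was 0.94. A ratio of the female parent to the reference is not given, since both were not well above background. On the same chromosome, sparse probes from 174850105 to 177826783 (20 probes over 2977 kb) were higher in the male parent, at 0.32 ± 0.036, and in progeny 2, at 0.30 ± 0.033 (SE over probes), than in the other mice, which lay between -0.0395 and 0.0358.

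Several further regions separated the female parent and progeny 5 and 6 from the other 5 mice. At 25417435 to 25432738 on chromosome 3 (3 probes) the female parent had a mean log2 ratio of -1.69 ± 0.29, progeny 5 of -1.52 ± 0.37 and progeny 6 of -1.58 ± 0.37 (SE over probes), with the others between -0.0108 and 0.0432. Short losses in the same 3 mice lay on chromosome 3 from 132548028 to 132551005, with -1.14 ± 1.01 (SE over 3 probes) in the female parent, and on chromosome 6 from 104236953 to 104242812, with -0.94 ± 0.88 (SE over 4 probes). Both errors were nearly the size of the mean, so the probes of these losses were not low alike. A gain on chromosome 8 from 102122727 to 102253497 (131 kb, 47 probes) had 0.29 ± 0.025 in the female parent, 0.27 ± 0.029 in progeny 5 and 0.29 ± 0.031 in progeny 6, and at most 0.0724 elsewhere. These 3 mice are those with X ratios near 1.

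In 4 of the 13 regions above the noise track, every mouse differed from the reference in the same direction. A 22.6 kb loss on chromosome 15 from 8344898 to 8367454 (11 probes) measured -0.60 ± 0.036 in the progeny (SD, n = 6), -0.60 in the male parent and -0.54 in the female parent. A loss on chromosome 7 from 133217428 to 133245332 (17 probes) measured -0.39 ± 0.058 in the progeny (SD, n = 6). A loss over 956 kb of chromosome 14 from 53428774 to 54384591 (102 probes) measured -0.25 ± 0.02, and a gain over 179 kb of chromosome 12 from 56189969 to 56368986 (35 probes) measured 0.27 ± 0.017 (SD, n = 6). The parents had -0.24 and -0.22 in this loss and 0.29 and 0.27 in this gain. Over the 956 kb loss, between 175 and 188 of the 204 readings of a mouse were well above background, and dimmer readings were kept as measured. Without dim probes its mean over progeny 2 to 6 was -0.28, against -0.25.

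**Figure D2:**
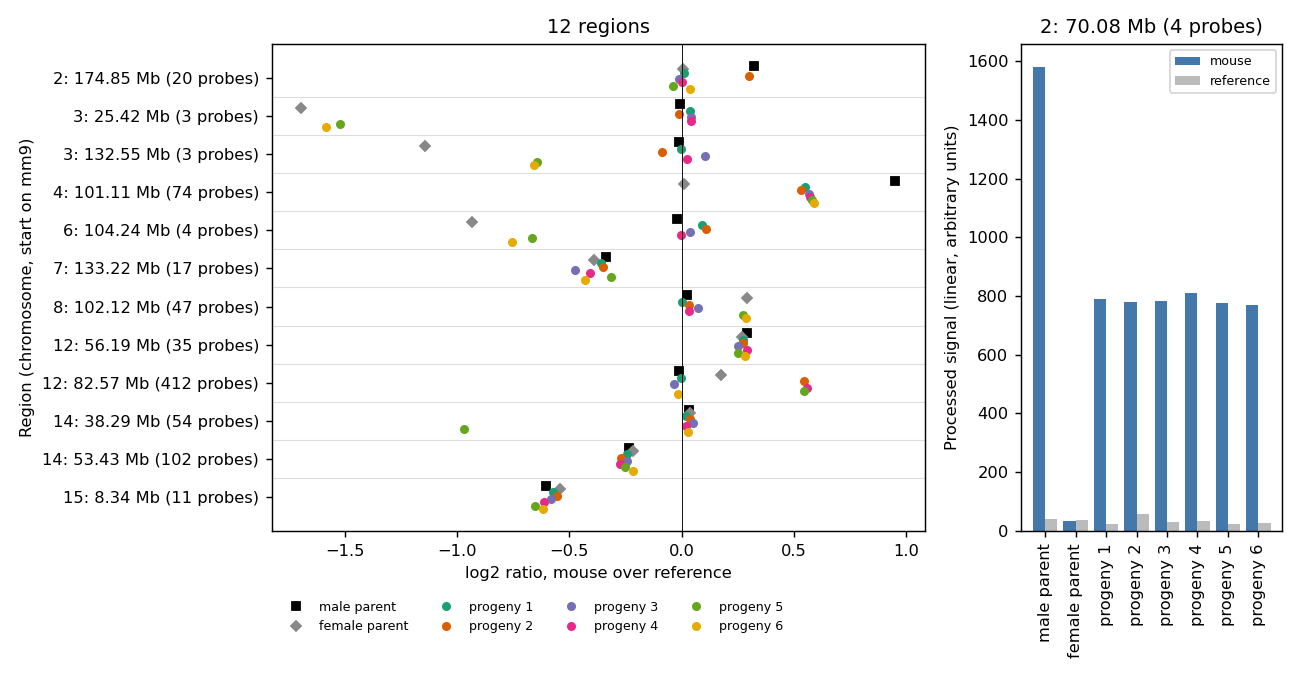
On the left, the mean log2 ratio of mouse over reference (horizontal axis) in each mouse (points) for 12 of the 13 regions that score above the noise track (listed by chromosome and start on mm9). On the right, bars give the mean processed signal (linear, arbitrary units) of mouse and reference for the chromosome 2 segment, where the reference was not well above background, with the male parent at 1579 and the progeny between 770 and 810.

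Over the whole genome, 1334 autosomal calls were made, 813 gains and 521 losses (60.9% gains, against 50% of calls above the noise track and 44.7% in the series table), from 89 in progeny 5 to 288 in progeny 2. The noise track gave 1051, which is 78.8% of that number. In some mice the calls were fewer than on their own noise track. These were progeny 1 (160 against 163), progeny 3 (103 against 129), progeny 5 (89 against 109) and progeny 6 (113 against 117). Gains and losses were uneven by mouse, such as 243 gains and 45 losses in progeny 2 against 36 and 130 in progeny 4. Calls of 3 probes made up 1077 of the total, against 923 on the noise track, while 50 calls held 10 probes or more, against 1. The calls formed 1214 regions, of which 400 were in a parent and in progeny, 178 in a parent only, 6 in all mice and 220 unclear in the parents. With scores above the noise track there were 52 calls in 13 regions, namely 7 in a parent and progeny, 4 in all mice, the chromosome 12 gain and the chromosome 14 loss. With normexp there were 280 calls, against 15 on the noise track.

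**Figure D3:**
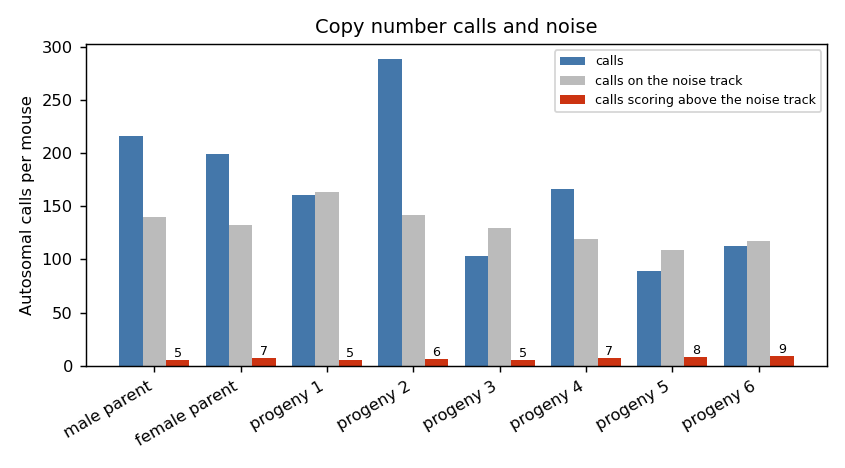
Number of autosomal calls per mouse (vertical axis) for each of the 8 mice, with bars for all calls, calls on the noise track and calls scoring above the highest noise score. The noise track reaches 109 to 163 calls per mouse, and between 5 and 9 calls per mouse score above it.

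Single probes were also compared, following the screen that the design text describes. In progeny and in neither parent, 2076 autosomal probes exceeded an absolute log2 ratio of 0.5 in the same direction on both arrays of a mouse, against 762 on the noise track. With normexp there were 445, against 8, and 3299 in the series table, against 1687. The chromosome 14 loss held 44 of them. Parents only had to lie within 0.25, so probes of the chromosome 12 gain, where the female parent had 0.17, could also enter. How many of them did was not counted. Progeny 3 had the most, with 643, and progeny 1 the fewest, with 171. Of the 5 strongest, 4 had a side that was not well above background on both arrays, so only bounds hold for them. On chromosome 7 at 56414696 to 56414755 progeny 1 was at least 1.77-fold above the reference, with a log2 ratio of 0.018 with normexp. On chromosome 2 at 84095536 to 84095595 the reference was at least 1.26-fold above progeny 1, and the log2 ratio was -0.051 with normexp. The probe measured on both sides, on chromosome 2 at 156671872 to 156671931 in progeny 3, had a mean log2 ratio of -1.68, with -0.60 and -2.77 on its arrays, and -0.91 with normexp.

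No autosomal probe differed between the 6 progeny and the 2 parents in limma after Benjamini-Hochberg adjustment, and 39501 of 950620 probes had an unadjusted p under 0.05. Group means were compared, so a change in a few progeny, or one inherited from 1 parent, can go unseen. No probe of the chromosome 14 loss or of the chromosome 12 gain passed either. The smallest p belonged to a probe on chromosome 12 at 117445915 to 117445974, where the progeny mean was -0.26 and the parents' mean 0.30, a difference of -0.56 ± 0.071 (SE), with an adjusted p of 1 in limma. With scan month as a block the count was again 0, with 30245 probes under an unadjusted p of 0.05, and within month 1 it was 0 with 45764. Without the male parent 6 probes passed and without the female parent 2.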

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

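All tests of explanations given here, with the bounds by which they were read, were chosen after the results had been seen, and so was the rule that picked signals of the series table (10 probes or more, not in all mice, sources apart by over 0.25).

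Among 19 values tested for a progeny mouse far from the other 5, 3 stood out. Progeny 5 stood apart at the chromosome 14 loss, with -0.97 against values near 0 in the others, and progeny 2 stood apart at the sparse probes of chromosome 2 from 174850105, with 0.30, where the male parent had 0.32; in the series table these were 0.024 and 0.018. Progeny 2 was also the lowest over the 6.1 kb segment of chromosome 2, with a log2 ratio of 3.68, of which only a bound of 6.54-fold holds. The reference there was well above background in 1 of 64 readings, which lay on an array of progeny 2, and the mouse signals themselves, from 770 to 810 in the progeny, held no such mouse. A chance rate of about 1 in 20 does not apply to regions that were called because a mouse deviated. The chromosome 14 loss was called in progeny 5 alone. The sparse chromosome 2 probes were called only in the male parent and progeny 2. These flags therefore add nothing to the calls.

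The series table held regions that differ from the scanner files of the same labels. A loss on chromosome 4 from 78453216 to 78509511 (18 probes) had a mean of -0.41 in its columns of the male parent and progeny 1, 3, 4 and 6. The chromosome 4 gain from 101110482 was called there in the male parent and progeny 5, at 0.58, and in none of the other progeny, whereas the scanner files show it in the male parent and all progeny. The chromosome 12 gain and the chromosome 14 loss were missing from it, and no mouse exceeded 0.0431 in absolute size over either, whereas the 4 regions shared by all mice had means within 0.0161 of those from the scanner files. Another processing of the same hybridisations is argued against by the median absolute correlation of 0.0318 between array-specific deviations of the same label. A candidate explanation is that the table holds other mice set against the same reference, although the labels with X ratios near 1 (female parent, progeny 5 and 6) are the same in both sources, so which source belongs to the labelled family stays open.

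The female parent's ratio of 0.17 over the chromosome 12 gain was 27.9% of the carriers' excess over the reference. DNA of the male parent or of progeny 1, 3 or 6 mixed into the female parent's sample is argued against by their own ratios there, between -0.0337 and -0.00509. DNA of progeny 2, 4 or 5 in that share is argued against by the chromosome 4 gain. It would have given at least 0.17 there, and the female parent had 0.0097 ± 0.014 (SE over probes). The chromosome 2 segment also argues against it, since a signal of at least 239 would be due and no reading was well above background. A ratio wave is argued against by the other windows of 412 probes in the same mouse, of which the highest reached 0.0507, and by flanks of 0.0164 and 0.0065. DNA of a male carrier from outside the family with 1 extra copy is argued against by 7 of 23 Y probes that lay below its share and by an X ratio of 0.94 where 0.78 would be due, but with 2 extra copies only 1 Y probe lay below the share and the X ratio due is 0.90, and over the 5 Y probes well above background in all mice the female parent had -0.63 against -1.61 and -1.41 in progeny 5 and 6. This stays open, as does a female carrier from outside, which was not tested, beside the hypothesis of a gain in part of the female parent's cells, for which the lowest of 8 parts of the region was at 0.14 and the highest at 0.20.

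Losses shared by the female parent and progeny 5 and 6 may reflect probes that also match Y sequence, since these mice have low Y ratios; a match to X would raise the ratio in them. Of 14 loci below -0.5 in the female parent and exactly 2 progeny, with the other mice within 0.25, 78.6% fell on this pair out of 15 possible pairs, and no other pair had more than 1. Autosomal differences inherited from the female parent would be spread over the pairs. Gains above 0.5 did not single out this pair, which held 3 of 10 high loci (30%), as many as the next pair. That cut lies above the chromosome 8 gain itself, at 0.27 to 0.29, so the count cannot test its source. The source stays open. The chromosome 8 gain was also found in the same labels of the series table, at 0.27, 0.25 and 0.26. Of the 13 probes of this pair, 100% were also low in the series table in the columns of the same labels, which have X medians near -1 as reference over mouse.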

How the results depend on the processing

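The limit at the highest noise score and the fit within scan month 1 were added after seeing the data. The number of calls and regions follows the settings. Signal over background limits the short calls in neither parent named in the results, and was not tested as the cause in other settings. Calls came to 280 with normexp, 497 without dim probes, 281 at z 8, 3452 at z 5, 544 with at least 5 probes, 722 at a log2 of 0.4, 804 with the mouse in Cy5 only, 684 in Cy3 only and 52 above the noise track. In the same order, regions came to 202, 414, 221, 3154, 476, 658, 710, 606 and 13. Regions in progeny and in neither parent came to 31, 88, 79, 1091, 162, 242, 230, 212 and 1, and to 863 in the series table, 630 with parents under 0.5 of the carriers and 762 after subtracting the median over the 8 mice. The noise track gave fewer than these with normexp (13), without dim probes (78) and at a log2 of 0.4 (224). It also gave fewer in the series table (767) and after subtracting the median (564). It gave more in the other settings except the limit at the noise track itself. With the mouse in Cy5 or Cy3 only, the track keeps copy number signal, so its count there is no measure of noise. Gains were 60.9% of calls, against 70.4% with normexp and 71.6% without dim probes, 44.7% in the series table, 50% above the noise track, and 34.7% and 67.8% with the mouse in Cy5 or Cy3 only. X regions came to 4 with normexp, 1 at z 5 and 1 in Cy3 only. Single probes came to 445 with normexp, 3299 in the series table and 128 over 0.8. The X ratio of the female parent was 0.74 with normexp and otherwise 0.91 to 0.97. Without each progeny mouse in turn, regions ranged from 963 to 1146 and those in neither parent from 308 to 381. The limma count ranged from 0 to 6 without each mouse in turn, the lone parent being assumed to vary like the progeny, and was 0 in every other fit, including all 16 arrays with dye and the mouse as a random block. With 0 probes in the real split, all 28 splits of the 8 mice into 6 and 2 reach it by construction, which says nothing about chance; the highest other split gave 3.

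Of 35 named regions and probes, 35 kept their value within the spread of the 2 arrays under the other centring, 12 with normexp, 12 in the series table and 30 after removal of slow waves, and 15 of 30 without dim probes; a single orientation cannot leave that spread by construction. Signs reversed in the series table for the chromosome 2 segment (-0.036), the chromosome 12 gain (-0.0047), the chromosome 14 loss (0.025), 5:139617571 (0.14), 5:71270811 (-0.21), 8:118282105 (-0.26) and 2:119435959 (0.066), and for single probes at 7:56414696 (-0.081), 2:84095536 (0.22) and 2:156671872 (0.024); the table's array-specific deviations do not follow the scanner files. The 3-probe loss at 3:105218183 reversed to 0.041 with normexp and to 0.073 without dim probes; the cause was not tested. The chromosome 14 loss was at -0.65 with normexp, and the chromosome 12 gain at 0.08 after removal of slow waves, whose window is little longer than the gain. The gene list tests and their alternatives were not run. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers.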

Other observations

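Over the chromosome 2 segment of 6.1 kb and the chromosome 4 gain of 160 kb the male parent stood above all progeny in the scanner files: it had 2.01 times the progeny mean signal over the former, and log2 ratios of 0.95 against 0.56 ± 0.02 (SD, n = 6) over the latter. All 6 progeny carried both, as did the male parent, and the female parent showed neither. In the series table the chromosome 4 gain was at 0.58 in the male parent, the level of the progeny in the scanner files, and in 1 of 6 progeny, and the chromosome 2 segment lay between -0.54 and 0.26 in the 8 mice.

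Progeny 5 had both the chromosome 14 loss and the chromosome 12 gain. It had the fewest calls, 89, against 109 on its noise track. Over the 5 Y probes well above background in all mice, the mean log2 ratio was -0.63 ± 0.45 in the female parent, -1.61 ± 0.39 in progeny 5 and -1.41 ± 0.36 in progeny 6 (SE over probes), and the female parent was the higher at 5 of 5 probes against either. The series table shows no such difference over its Y medians, whose background is unknown: as reference over mouse they were 3.54 and 3.08 in the female parent, 3.42 and 3.17 in progeny 5 and 3.32 and 3.57 in progeny 6.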
